A study of Nicotiana tabacum with 9 samples.

How the data were processed

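Leaves of the cigar tobacco variety H382 (Nicotiana tabacum, an allotetraploid) at the seedling stage were profiled by RNA sequencing at 3 light intensities, 50, 100 and 200 µmol m-2 s-1, with 3 biological replicates each, 9 libraries in all. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name CASAVA 1.7, HISAT and HTSeq. The genome build is not given in the sources used here, and the gene identifiers begin with Nitab4.5. This kit does not mark strand, so reads from a gene and from an overlapping or antisense partner cannot be told apart. Reads of near-identical copies cannot be placed on a single copy with certainty. Examples are the chlorophyll a-b binding proteins, the phenylalanine ammonia-lyases and the protochlorophyllide reductases. Values of single members are uncertain for that reason.

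The table analysed here holds 123 genes. It gives read counts per gene and library, which are the authors' raw deposited counts, per the file headers. It also gives FPKM values made by the authors, per the file headers, and the authors' log2 fold changes, p-values and adjusted p-values for each pair of groups, per the file headers. The authors' deposited table marks 122 of the 123 genes as changed between 50 and 200 µmol m-2 s-1. The genes were therefore chosen, by a rule not given in the sources used here, so that nearly all differ between these same samples, and no count of calls below is independent evidence that light changed them. The authors' adjusted p was up to 30470 times their p, so their adjustment covered at least 30470 genes, whereas adjustment here covers 123.

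Dividing count by FPKM and gene length gave a single library total for all genes, between 12395758 and 16603534 reads. The table's genes held 7.05% ± 0.40 of reads at 50, 6.13% ± 0.25 at 100 and 5.09% ± 0.40 at 200 µmol m-2 s-1 (SD, n = 3). The authors' mean normalised counts gave their size factors, with a largest relative error of 5.0e-10. The factors of the separate comparisons were combined into 1 set of 9, from which they differed by at most 0.19%.

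Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided) on all 9 libraries, with group as the only factor, filterByExpr, which kept all 123 genes, and Benjamini-Hochberg adjustment at 0.05. Effective library sizes came from the authors' size factors. This departs from the design fixed before the data were examined, which named TMM factors. TMM takes most genes of a table as unchanged, and here nearly all genes had been chosen as changed. The departure was decided after the calls under 5 scalings (the authors' factors, library totals, TMM, RLE and median centring) had been seen, so the TMM value stands beside each count of calls over the whole table in the results. Against the authors' factors, TMM raised the median log2 change of all genes by 0.43 for 200 against 50, by 0.28 for 100 against 50 and by 0.14 for 200 against 100. Levels are CPM values on the effective library sizes.

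The comparisons were the 3 pairs of groups, any difference among the 3 groups, a linear trend in log2 light intensity, and the step difference, which is the log2 change from 100 to 200 minus that from 50 to 100. Of 22 gene lists fixed before the data were examined, 15 had at least 1 member in the table and 4 had at least 5. Those 4 were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks only whether a list's genes move on balance one way. Their background is the 123 chosen genes. The list tests were planned for the pairs of groups, and those on the step difference were added after seeing the data. The lists for photosynthetic electron carriers, photorespiration, the respiratory chain, light signalling and clock, heat shock proteins, glandular trichome markers and ribosomal proteins had 0 members.

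Genes were named by a rule fixed before the data were examined. For each pair of groups it took the 5 largest rises and 5 largest falls among called genes with a product name, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups, 1 gene per product name. For 200 against 50 it added the called member of smallest p in each direction of each list, skipping genes already named, up to 20. Product names are those of the table. The reference gene table matched 0 of its identifiers. Coordinates are as the table gives them.

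No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom between 23.58 and 102.44), so all were counted as separate samples. On 20 simulated data sets of 200 against 50, 60 of 123 genes were changed, with rises and falls in equal number. The edgeR step recovered 67.5% of genes changed 1.5-fold and 96.5% of genes changed 2-fold, and 1.84% of calls were false. The simulated counts were made and fitted with the same library sizes, and their genes were not chosen as changed. These shares therefore do not cover errors from the scaling or from the choice of genes. The alternatives were a replicate block, each library left out in turn, no filter and a stricter filter of 50 reads in 3 libraries, RLE factors, DESeq2 1.42.0, a fold of at least 2, the 2 compared groups alone, and a replicate block with median centring. TMM within the table, library totals and median centring alone were chosen after seeing the data. Changes of pseudocount did not apply to counts.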

Results

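Leaf transcripts of cigar tobacco H382 seedlings were compared at 50, 100 and 200 µmol m-2 s-1 (light 50, light 100 and light 200), with 3 libraries per group. Library totals were 12395758, 15374035 and 14939891 reads at light 50, 14887372, 13743796 and 16603534 at light 100, and 15022764, 14253291 and 16061435 at light 200. Counts of the 123 genes ranged from 8 to 136456 reads. P-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over these 123 genes, which had been chosen on these samples. Those of gene lists are from camera or fry, adjusted over the 4 tested lists within each comparison.

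The first comparison asks which leaf transcripts differ between the lowest and the highest light. Genes of phenylpropanoid and flavonoid synthesis were higher at light 200 and genes of the photosynthetic antenna and photosystems were lower. All 10 measured members of the phenylpropanoid and flavonoid list rose, with a median log2 change of 2.51. Anthocyanidin 3-O-glucosyltransferase (Nitab4.5_0000403g0080, Nt19, 35855585 to 35857000), which adds glucose to anthocyanidins, rose from 8.88 ± 2.39 to 140.4 ± 32.0 CPM (SD, n = 3), a log2 change of 3.98 ± 0.26 (SE; adjusted p = 1.06e-07). Probable chalcone--flavonone isomerase 3 (Nitab4.5_0000375g0270, Nt13, 11234714 to 11237111) rose from 15.7 ± 5.63 to 248.8 ± 29.6 CPM. Flavonol synthase/flavanone 3-hydroxylase (Nitab4.5_0005357g0020, Nt12, 40715554 to 40722943) rose by a log2 change of 2.58 ± 0.17 (SE).

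All 9 light-harvesting antenna genes, all 5 photosystem I genes and all 5 photosystem II genes fell at light 200, with median log2 changes of -0.90, -0.97 and -0.62. The photosystem II member listed as D2 protein (Nitab4.5_0000220g0160) is uncertain, since this protein is normally encoded in the plastid and the listed gene is on Nt19 at 6.75 ± 1.11 CPM at light 50 and 3.36 ± 0.73 at light 200. It had the largest fall of that list, with a log2 change of -1.01. Chlorophyll a-b binding protein 16 (Nitab4.5_0000982g0200, Nt14, 109835123 to 109846561), an antenna protein, fell from 1133 ± 182 to 283.2 ± 37.4 CPM, a log2 change of -2.0 ± 0.16 (SE; adjusted p = 3.99e-07). Photosystem I reaction center subunit V (Nitab4.5_0001622g0160, Nt01, 124276760 to 124277203) had a log2 change of -1.34 ± 0.14 (SE). Oxygen-evolving enhancer protein 3 (Nitab4.5_0002345g0070, Nt17, 171219568 to 171221535), a subunit on the water-splitting side of photosystem II, fell from 5943 ± 346 to 3482 ± 461 CPM. The 3 measured members of the chlorophyll synthesis list, all protochlorophyllide reductases, fell, the named one (Nitab4.5_0001320g0160, Nt01, 129185978 to 129189772) by a log2 change of -1.98 ± 0.24 (SE). Counts adjusted over the list alone were the same for each of these 5 lists, and the lists are not independent evidence, since the genes were chosen on these samples. With the preset correlation, camera gave adjusted p = 6.3e-07 for the phenylpropanoid list, 0.00361 for the antenna list, 0.0468 for photosystem I and 0.125 for photosystem II. The photosystem I call was lost in 6 of the 9 fits without 1 library (adjusted p from 0.0517 to 0.0669). None was called with an estimated correlation (adjusted p = 0.272 for the phenylpropanoid list and adjusted p = 0.384 for the other 3).

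**Figure D1:**
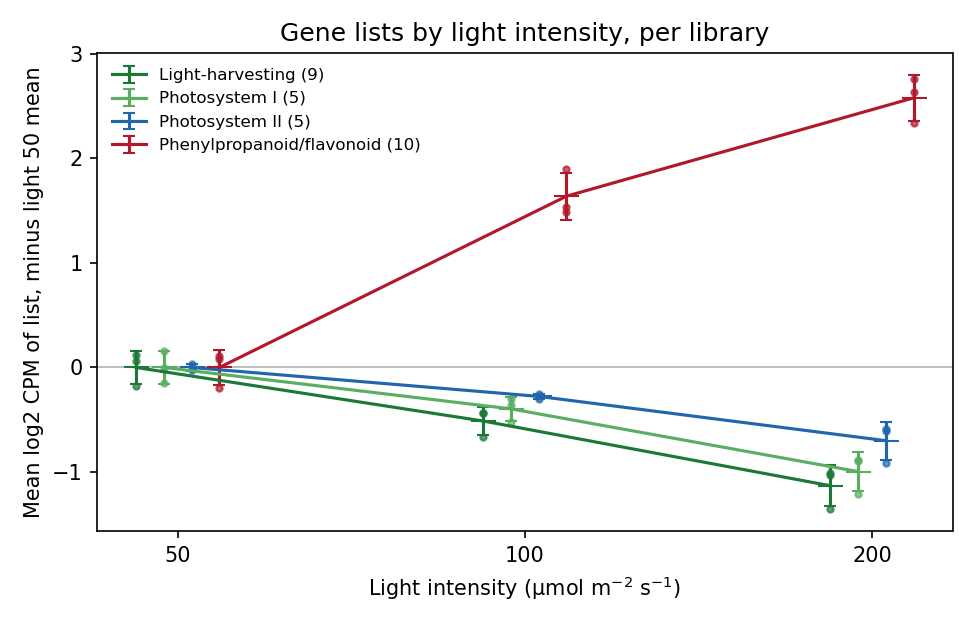
Mean log2 CPM of the members of 4 gene lists in each library, relative to the light 50 mean, against light intensity in µmol m-2 s-1. Points are libraries, bars are the mean ± SD (n = 3), and numbers in the legend are list members. The phenylpropanoid and flavonoid list had a mean log2 change of 2.58 at light 200, and the antenna list one of -1.13.

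Starch-related and photoprotective transcripts also differed. Glucose-1-phosphate adenylyltransferase large subunit 1 (Nitab4.5_0000308g0330, Nt19, 76942735 to 76946994), of the enzyme that makes the glucose donor for starch, rose from 48.5 ± 8.63 to 519.6 ± 88.9 CPM. Granule-bound starch synthase 2 (Nitab4.5_0002980g0050, Nt03, 90247218 to 90253959) rose 4.86-fold, so both measured members of the starch and sucrose list rose. Early light-induced protein (Nitab4.5_0000977g0030, Nt14, 113456482 to 113458425) rose 5.43-fold, while zeaxanthin epoxidase (Nitab4.5_0002016g0120, Nt17, 145236523 to 145243444), which turns zeaxanthin back to violaxanthin, had a log2 change of -0.67 ± 0.13 (SE). These were the 2 measured members of the photoprotection list.

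Lists with few members are given by gene. Pyruvate kinase isozyme A (Nitab4.5_0000772g0060) rose by a log2 change of 1.36 ± 0.22 (SE) and glutamine synthetase (Nitab4.5_0001650g0160) by 0.66 ± 0.21. GH3.10 (Nitab4.5_0002370g0050), named as an auxin-conjugating enzyme, rose by 1.13 ± 0.34. All 3 genes of the defence, wounding and jasmonate list rose. GH3.10 is counted there too, and another is linoleate 9S-lipoxygenase 5 (Nitab4.5_0000137g0100), which rose by 0.85 ± 0.15. Catalase isozyme 1 (Nitab4.5_0000407g0130), which removes hydrogen peroxide, fell from 3471 ± 574 to 1287 ± 212 CPM. Rubisco activase 1 (Nitab4.5_0004475g0020) had a log2 change of -0.70 ± 0.14 (SE). The cell division and nicotine lists, meant as markers of other tissue, held 1 gene each. Both were matched by product name only, so neither gene is shown here to mark a tissue. The tubulin beta-1 chain (Nitab4.5_0001951g0080), on the cell division list, fell 3.27-fold, and berberine bridge enzyme-like 8 (Nitab4.5_0000009g0310), on the nicotine list, rose from 0.941 ± 0.359 to 5.58 ± 1.78 CPM. Median centring ended the calls of the lipoxygenase, GH3.10 and glutamine synthetase (adjusted p = 0.11, 0.087 and 0.334), and TMM that of Rubisco activase 1 (adjusted p = 0.0787).

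The largest log2 rise by the naming rule was that of UDP-glycosyltransferase 86A1 (Nitab4.5_0003524g0010, Nt24, 28269879 to 28270736), from 0.932 ± 0.347 to 29.0 ± 9.14 CPM, with as few as 8 reads in a library. The largest falls were those of subtilisin-like protease SBT1.9 (Nitab4.5_0002388g0020, log2 change -3.03 ± 0.27, SE), TLD domain-containing protein 1 (Nitab4.5_0001988g0020, -2.54 ± 0.26), CSC1-like protein ERD4 (Nitab4.5_0000315g0120, -2.38 ± 0.39), thiosulfate sulfurtransferase 16 (Nitab4.5_0001696g0140, -2.28 ± 0.48) and a KIN2-like stress-induced protein (Nitab4.5_0003384g0010, -2.23 ± 0.47).

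In all, 58 genes were higher and 64 lower at light 200 than at light 50, the same numbers the authors' deposited table marks. With TMM, the scaling fixed beforehand, 59 were higher and 48 lower, and with median centring 41 and 64. The gene called in neither direction, DRT100 (Nitab4.5_0000213g0030), had 21.8 ± 3.99 CPM at light 50 and 24.0 ± 4.98 at light 200.

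The second comparison covers the first doubling of light, from 50 to 100. The phenylpropanoid and flavonoid list rose again, in all 10 members, with a median log2 change of 1.7. Antenna genes fell in 9 of 9 members and photosystem I genes in 5 of 5, with medians of -0.46 and -0.40. Photosystem II genes fell in 2 of 5, and in 0 of 5 when adjusted over the list alone. The uncertain D2 protein was 1 of the 2 (adjusted p = 0.035). These falls depended on the scaling. With TMM, 2 of the 19 antenna and photosystem genes were called lower and 4 had a positive change, with a median of -0.10. UDP-glycosyltransferase 86A1 rose 18.7-fold and 1-aminocyclopropane-1-carboxylate oxidase (Nitab4.5_0000091g0420, Nt14, 98536509 to 98538581), which makes ethylene, rose from 99.3 ± 15.8 to 355.1 ± 30.2 CPM. TLD domain-containing protein 1 fell by a log2 change of -1.85 and the named protochlorophyllide reductase by one of -1.12. ERD4 fell by a log2 change of -1.66, the tubulin beta-1 chain by one of -1.18 and thiosulfate sulfurtransferase 16 by one of -1.48, and the call of the last was lost with TMM (adjusted p = 0.0792) and without light 50 replicate 1 (adjusted p = 0.0651). In all, 52 genes were higher and 50 lower. With TMM 58 were higher and 13 lower, and with median centring 32 and 63. The number lower fell to 29 without light 50 replicate 1 and to 31 without light 100 replicate 1. The authors' deposited table marks 29 as higher and 15 as lower, after adjustment over more genes. Camera gave adjusted p = 4.43e-07 for the phenylpropanoid list and 0.0108 for the antenna list, and neither was called with an estimated correlation (adjusted p = 0.244 and adjusted p = 0.485).

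The third comparison covers the second doubling, from 100 to 200. Phenylpropanoid and flavonoid genes rose in 8 of 10 members (10 when adjusted over the list alone), with a median log2 change of 0.92. Antenna genes fell in 9 of 9, photosystem I genes in 5 of 5 and photosystem II genes in 4 of 5, with medians of -0.50, -0.52 and -0.40. With RLE factors, 5 of these 19 genes were called lower. Early light-induced protein rose 2.3-fold, from 63.0 ± 12.7 to 145.1 ± 22.4 CPM, and naringenin,2-oxoglutarate 3-dioxygenase (Nitab4.5_0000864g0050), a flavanone hydroxylase, by a log2 change of 1.14. Berberine bridge enzyme-like 8 rose by a log2 change of 1.73. SBT1.9 fell from 38.2 ± 3.83 to 8.72 ± 3.65 CPM, and chlorophyll a-b binding protein P4 (Nitab4.5_0007189g0010, Nt22, 8664153 to 8666436) by a log2 change of -1.13. The isomerase FKBP17-2 (Nitab4.5_0008639g0010), beta-xylosidase/alpha-L-arabinofuranosidase 2 (Nitab4.5_0003089g0010) and the mitochondrial L-3-cyanoalanine synthase/cysteine synthase 2 (Nitab4.5_0000583g0180) fell by log2 changes of -1.37, -1.11 and -1.05. In all, 26 genes were higher and 48 lower. With TMM 43 were higher and 36 lower, with RLE 45 and 17, with library totals 42 and 42, and with median centring 14 and 56. The authors' deposited table marks 14 as higher and 25 as lower. The count of 74 fell to 40 (13 higher, 27 lower) without light 100 replicate 3 and to 46 (15 higher, 31 lower) without light 200 replicate 1. Camera gave adjusted p = 1.23e-06 for the phenylpropanoid list, 0.00273 for the antenna list and 0.0257 for photosystem I, and none was called with an estimated correlation (adjusted p = 0.258, adjusted p = 0.351 and adjusted p = 0.351). The photosystem I call was also lost without light 100 replicate 2 (adjusted p = 0.0602).

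Across the 3 light intensities, 122 genes differed and 122 had a trend in log2 light intensity, 58 upward and 64 downward. With TMM 103 genes differed and the trend was upward in 59 and downward in 45. With median centring 100 differed, 36 of them higher and 64 lower at light 200 than at light 50, and the trend was upward in 38 and downward in 64. The light 100 mean lay between the other two for 56 of the 58 genes that rose from light 50 to light 200 and for 64 of the 64 that fell. The 2 doublings shared 21 genes called higher and 37 called lower, with 0 called in opposite directions. With TMM they shared 42 higher and 9 lower, with RLE 39 and 13, with library totals 37 and 29, and with median centring 10 and 55. The shared calls numbered 23 higher and 23 lower without light 50 replicate 1 or without light 100 replicate 2, 14 and 17 without light 100 replicate 1, 10 and 15 without light 100 replicate 3, and 13 and 25 without light 200 replicate 1. Independent lists of these sizes would share 11 and 19.5, and unchanged groups simulated with the same shared light 100 libraries shared 0. The covariance of the log2 changes was 0.53, against -0.025 in the simulation. The genes had been chosen on the change from light 50 to light 200, which is the sum of the 2 doublings, so neither the independent nor the simulated values are a fair reference, and no excess over them is read.

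The step difference asks whether the 2 doublings changed a gene by different amounts. It was called for 3 genes, all with the larger rise in the first doubling: UDP-glycosyltransferase 86A1, 1-aminocyclopropane-1-carboxylate oxidase and anthocyanin 5-aromatic acyltransferase (Nitab4.5_0001256g0060), the last of which had 7.59 ± 0.147, 24.2 ± 2.94 and 31.3 ± 4.37 CPM at the 3 intensities. With TMM 23 genes were called and with DESeq2 16, and 19 had an unadjusted p under 0.05 in edgeR. All 23 calls with TMM were negative, and TMM moved the median step difference of all genes from -0.17 to -0.31. With the authors' factors the edgeR count was 14 without light 50 replicate 1, and 1 without light 100 replicate 2 or without light 200 replicate 2. Choosing genes as changed between light 50 and light 200 can favour a small spread within groups, so step calls may be too many. The median step difference of the phenylpropanoid and flavonoid list was -0.74, with 1 of 10 members called (4 when adjusted over the list alone). Camera, run on the step difference only after the data were seen, gave adjusted p = 0.0204 for this list. It was not called with an estimated correlation (adjusted p = 0.998) or by fry (adjusted p = 0.21), nor by camera without light 50 replicate 1 (adjusted p = 0.0598), light 100 replicate 2 (adjusted p = 0.315) or light 200 replicate 3 (adjusted p = 0.0713).

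**Figure D2:**
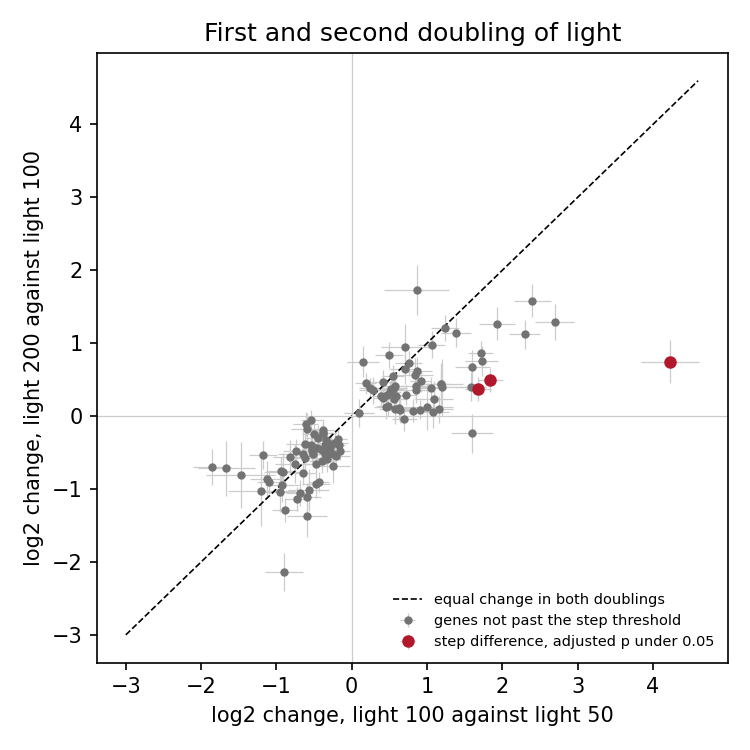
Log2 change from light 100 to light 200 against that from light 50 to light 100 for each of the 123 genes, with standard errors as bars and equal change as the dashed line. The 3 genes with a step difference are in red, to the right of the line; UDP-glycosyltransferase 86A1 is at 4.22 and 0.75.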

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

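Apart from the test of the step difference and the counts over other groupings of the libraries, the tests in this part were chosen only after the results were seen, and so was the bound of 2 standard errors used for the bend. A difference between the 2 doublings of light was called for 3 genes by the test of the difference itself. The step difference was -3.48 for UDP-glycosyltransferase 86A1 (adjusted p = 0.00426, edgeR), -1.34 for 1-aminocyclopropane-1-carboxylate oxidase (adjusted p = 0.0189) and -1.30 for anthocyanin 5-aromatic acyltransferase (adjusted p = 0.0225).

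Among the 58 genes that rose from light 50 to light 200, the median log2 change was 0.85 in the first doubling and 0.40 in the second, and 49 had a negative step difference. Among the 64 that fell, the medians were -0.51 and -0.52. The mean log2 level of genes that rose minus that of genes that fell cannot be moved by any scaling of a library. It bent by -0.479 ± 0.181 (SE) over all 9 libraries. This argues against equal change in the 2 doublings for both sets under any scaling. It cannot say which set bends, since another scaling of the light 100 libraries moves the step difference of both alike. Scaling as the source of the larger first change among genes that rose therefore stays open. With 1 library left out the bend lay between -0.598 and -0.311. Without light 100 replicate 2 it was -0.311 ± 0.173 (SE), within 2 standard errors of 0. In the other fits it was -2.26 to -3.16 standard errors from 0. Each fit had only 5 degrees of freedom, for which a bound of 2 standard errors is lenient. Passing that bound is therefore weak evidence that the bend outlasts the loss of a library. Without light 100 replicate 2 the step difference was called for 1 gene, so a single library as the source stays open. A response to light that levels off may remain as a hypothesis, and so does any other difference between the growth conditions of the 3 groups.

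Photosynthesis genes fell and phenylpropanoid genes rose at light 200. Under 4 other scalings the median log2 change of the 19 antenna and photosystem genes came no nearer 0 than -0.46, and that of the phenylpropanoid list went no lower than 2.01, which argues against scaling as the whole source of either. The smaller share of reads in the table's genes could force other genes up by a log2 change of only 0.030. Reads given up by genes outside the table are not covered by that value. A smaller share of photosynthetic cells would lower these 19 genes by a common factor if all were equally specific to those cells. Their log2 changes, from -2.0 to -0.50, differed by more than their standard errors (Cochran's Q = 123.0 on 18 degrees of freedom, 95% point 28.9), which argues against a common factor as the only source; a shift in cell makeup acting on genes of unequal specificity stays open.

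Only 10 splits of 6 libraries exist, too few for a share under 0.05. The real split called 122, 102 and 74 genes for 200 against 50, 100 against 50 and 200 against 100, and 1 split, the real one, reached that count in each; the highest other counts were 0, 0 and 1. Of 100 drawn splits of the 9 libraries into groups of 3, 1 called as many as 122 genes among the 3 groups and 1 as many for the trend, the real one in each case, and the highest others were 96 and 112. The genes had been chosen for differing between light 50 and light 200 in these libraries, which by itself puts the real grouping first, so these counts do not bear on chance, and the bound of 0.05 set for them beforehand does not apply. For the step difference 3 of 100 splits, the real one included, called 3 or more. Splits that mix light intensities within a group widen the spread there, so this share does not bear on chance either. The highest other called 92, many times the real count. That split had all 3 light 200 libraries in the place of the middle group, so its contrast set light 200 against the light 50 and light 100 libraries. The next, with 39 calls, had 2 light 200 libraries there. Both counts therefore carry the change with light itself and are no reference for the step difference.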

How the results depend on the processing

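As alternatives, TMM within the table (fixed beforehand as the main scaling), library totals, median centring alone and the list tests on the step difference were chosen after seeing the data. The counts for light 200 against light 50, light 100 against light 50, any difference and the trend stayed within 1.5 times under every alternative except a fold of at least 2, while the split into higher and lower calls moved with the scaling and, for 100 against 50, with single libraries, as given beside each count. With a fold of at least 2, 66 genes were called for 200 against 50, 29 for 100 against 50, 15 for 200 against 100, 66 among the groups and 66 for the trend (fold over the whole range), and the 2 doublings shared 6, since that threshold removes smaller changes. The step difference, called for 3 genes, was called for 6 with the replicate block and 5 with the block and median centring. It was called for 16 with DESeq2, 23 with TMM and 5 with library totals. TMM moved the median step difference of all genes from -0.17 to -0.31, the direction of all 23 of its calls. The cause was otherwise not tested. With 1 library left out, the step count ranged from 1 to 14, the count for 200 against 100 from 40 to 80 and the overlap of the 2 doublings from 25 to 58; the cause was not tested. The replicate block left the count for 200 against 50 at 122. Same-numbered libraries did not deviate together (correlations of -0.44 to 0.55 over 9 pairs, 4 over 0.1, and 1 of 9 libraries correlating best with its own number in both other groups), so the numbers were not taken as pairs.

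Every camera call of a list, for the 3 pairs of groups and the step difference, was lost with an estimated correlation: antenna medians of -0.903, -0.462 and -0.495 (adjusted p = 0.384, 0.485 and 0.351 for 200 against 50, 100 against 50 and 200 against 100), photosystem I medians of -0.968 and -0.522 (0.384 and 0.351 for 200 against 50 and 200 against 100), and phenylpropanoid medians of 2.506, 1.695 and 0.924 (0.272, 0.244 and 0.258). The phenylpropanoid call for the step difference (-0.741, adjusted p = 0.998 with that correlation) was also lost with fry (0.21) and without light 50 replicate 1, light 100 replicate 2 or light 200 replicate 3 (range without 1 library -0.936 to -0.460). The antenna step median, not called, turned to 0.033 with RLE (camera adjusted p = 0.643), since RLE moved the median step difference of all genes from -0.17 to -0.01. Fry called photosystem II in all 3 comparisons (medians -0.622, -0.183 and -0.398) and photosystem I for 100 against 50 (-0.397), where camera had not. Photosystem I for 200 against 50 was lost with the replicate block (-0.966, adjusted p = 0.0637) and in the fits without light 50 replicate 1 or 3, light 100 replicate 1, 2 or 3, or light 200 replicate 3 (adjusted p from 0.0517 to 0.0669; medians over all fits without 1 library from -1.046 to -0.834), and for 200 against 100 without light 100 replicate 2 (range -0.592 to -0.403). Median centring added photosystem II for 200 against 100 (-0.640, adjusted p = 0.0423). With TMM the photosystem II median for 100 against 50 turned to 0.10 (camera adjusted p = 0.334), since TMM raised the median log2 change of all genes by 0.28 there. Of the named genes' values under other settings, leaving the fold threshold aside, 847 kept their call, 8 lost it and 0 turned direction. Depth limited few genes, since the lowest count was 8 reads, in UDP-glycosyltransferase 86A1. The pseudocount alternative did not apply to counts and was not run.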

Other observations

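All groups and tests in this part were chosen after the values were seen, on genes that had themselves been chosen on these samples. From product names 6 groups were formed, 5 of which share genes with the fixed lists. All 5 genes of starch building and breakdown rose from light 50 to light 200, with a median log2 change of 1.63, and so did all 6 UDP-sugar glycosyltransferases, with a median of 2.41. Fisher's exact test, two-sided against the other genes of the table, gave p = 0.0212 and p = 0.00952 (adjusted over the 6 groups, 0.0424 and 0.0286). Of these genes, 2 of the 5 and 2 of the 6 belong to the starch and the phenylpropanoid lists. Without the genes of those lists, the 3 and 4 left gave Fisher's exact p = 0.0963 and p = 0.0302 (adjusted over 5 groups, 0.241 and 0.151), so whether either group stands apart beyond the lists was left undecided. The 3 genes of the abscisic acid and xanthophyll route, 1 of them on the photoprotection list, and the 3 protochlorophyllide reductases, which are the whole chlorophyll list, fell, which Fisher's exact test did not set apart from other genes (p = 0.246 for each, adjusted 0.295). Of the 5 genes of cysteine and sulfur metabolism, 2 rose and 3 fell (Fisher's exact p = 1).

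Products named as chloroplastic made up 53.1% of the 64 genes that fell and 20.7% of the 58 that rose (Fisher's exact test, two-sided, p = 0.000366, adjusted 0.0022). Of the 34 such genes that fell, 18 belong to the antenna and photosystem lists. Without the 19 genes of those lists, the shares were 35.6% of 45 and 20.7% of 58 (Fisher's exact p = 0.119), and without the genes of every list this group shares members with, p = 0.31 (adjusted 0.517), so a link beyond these lists was left undecided.

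A hypothesis that flavonoid-branch genes rose more than general phenylpropanoid genes was left undecided. With the 2 phenylalanine ammonia-lyases and the flavone 3'-O-methyltransferase set against the other 7 members, mean log2 changes were 1.65 and 2.97 (exact permutation test, two-sided, p = 0.025). With the methyltransferase counted as flavonoid, as its name says, the difference was 1.02 (exact permutation p = 0.156). The answer depends on where that 1 gene is placed.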
